A study of Rattus norvegicus with 6 samples.

How the data were processed

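RNA from the inner epithelial layer of the colon of 6 adult male Wistar rats without a pineal gland was sequenced, 3 given melatonin and 3 given vehicle. Per the labels' protocols, polyadenylated RNA was captured with oligo(dT) beads, fragmented and primed with random hexamers, and no strand marking is described there, so a gene and its antisense partner are not told apart. Each animal was its own sample, and vehicle animals carry the numbers 1 to 3 and melatonin animals 4 to 6.

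The deposited table gives FPKM values (fragments scaled by transcript length and by the mapped total of the library), made by the authors for each RefSeq transcript and animal and rounded to 2 decimals, per the file headers and the values. The submitters' processing notes name BWA 0.7.10-r789, Bowtie2, RSEM and the rat build rn6, without saying which did what. The annotation release and the handling of reads that fit several transcripts are not given in the sources used here. The authors' deposited table also gives the log2 ratio of the group means, in which a value of 0 FPKM was set to 0.01 before the ratio was taken. The recomputed means differed from theirs by at most 3.33e-06 and the recomputed ratios by at most 4.93e-08. It further gives a score per transcript, headed as a probability in the authors' file, from a tool not given in the sources used here. The tests below use the FPKM values alone, and the other columns serve only where the authors' table is named.

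The planned test took estimated read counts as its first choice, and FPKM was the stated second. The table holds FPKM and no counts, so the second was used. FPKM values were not scaled further. Transcripts were matched by accession to gene symbols of the RefSeq rat annotation (GRCr8, used for names only, with no coordinates), which matched 12883 of 13647, and values of transcripts of 1 gene were summed. This gave 12340 genes, 385 of them with more than 1 transcript, and 764 unmatched transcripts were kept as they were, 13104 features in all. Summing was chosen after the layout of the table was seen and before any test result. Features with a mean FPKM of at least 1 over the 6 animals were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend, two-sided) on log2(FPKM + 1), with Benjamini-Hochberg adjustment over the 10137 features tested and a threshold of 0.05. Fold changes on this scale understate the change of genes with low values.

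39 gene lists, 23 of pathways and 16 of cell types that a scrape of colonic epithelium could hold, were fixed before the data were examined, as were the tests, the main alternatives and the rule for named genes. Of these lists, 30 had at least 5 tested members and were tested with limma camera (preset inter-gene correlation 0.01, two-sided, Benjamini-Hochberg over the 30), 8 had fewer and 1 had no member in the table. Camera with an estimated correlation and the fry rotation test were run beside it. For the lists called, the number of members past 0.05 is given over all genes and adjusted over the list alone. The rule for named genes took up to 12 genes per direction past the threshold and, where fewer than 10 passed, filled up to 10 by smallest p. It added Per1, Per2, Nr1d1, Dbp, Bmal1, Mtnr1a and Mtnr1b, and up to 4 members with the smallest p from each list described. Unmatched transcripts and symbols that begin with LOC or RGD were passed over. Some genes that the rule takes are not reported here.

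The depth was estimated from the low values. In short transcripts the FPKM values fall on steps, and with 41 bases taken off each transcript's length, 86.3% to 94.0% of the values used lay within 0.1 of a whole number of reads. The step sizes give 3390000 to 3700000 mapped fragments per library. This is an estimate made here. RSEM divides reads between transcripts, so not every value is a whole number of reads. The 10 transcripts with the highest values took 8.0% to 9.8% of the summed FPKM in each library.

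The procedure was tested on simulated data for the comparison of melatonin with vehicle. FPKM values were drawn for a mean of 10030 tested features, with the fitted means and spreads, and 200 genes with at least 5 FPKM were changed in each of 5 runs. limma called 84.2% of the genes changed by 1 on the log2 scale and 99.8% of those changed by 2, and 5.3% of all calls were false. The simulated noise was independent between genes, so it does not stand for animals that differ in whole groups of genes. Its spreads were those moderated by limma, and 200 changed genes per run make the Benjamini-Hochberg threshold easier to pass. The shares called therefore do not carry over to data with few changed genes.

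The alternatives were 2 other scalings, 2 other filters, another pseudocount, voom on estimated reads with and without sample quality weights, a looser threshold, leaving out each animal, unsummed transcripts, and leaving out transcripts under 200 bases. Scalings and the stricter filter planned for a count model were carried over to FPKM values in limma, and no count model was run. Figures were drawn with matplotlib 3.10.9, and tables were prepared with pandas 2.3.3 in Python 3.11.15.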

Results

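Gene expression was measured in the inner epithelial layer of the colon of 6 adult male Wistar rats whose pineal gland had been removed. Removal of the gland takes away its nightly output of melatonin, so that a single injected dose can be followed without that output. 3 animals received melatonin (1 mg/kg, intraperitoneal) and 3 received vehicle (2.5% ethanol in PBS) at the start of subjective night, and tissue was taken 4 h later. The RNA integrity numbers lay between 9.0 and 9.7. The table held 13647 RefSeq transcripts as FPKM values in each animal. The depth, estimated from the steps between low FPKM values, was 3390000 to 3700000 mapped fragments per library. Between 12057 and 12323 transcripts lay above 0 in each library. A tested gene had a median of 125 estimated reads per library, so genes near 1 FPKM rest on few reads.

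The comparison of melatonin with vehicle asks which genes of the colonic epithelium respond to the hormone within hours. The genes with the smallest p-values among those higher after melatonin included Acaa2 (mitochondrial 3-ketoacyl-CoA thiolase), the protease inhibitors Serpina3n and Slpi, and Tnfsf10, the death ligand TRAIL. Among those lower were the clock genes Per1 and Dbp, the hormone-responsive transcription factor Klf9 and the inducible heat shock gene Hspa1a. None of them passed the threshold. With limma on log2(FPKM + 1) over 10137 genes and unmatched transcripts, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.182. At an unadjusted p under 0.05 there were 380, of which 185 were higher and 195 lower, where chance alone gives 507. Without melatonin animal 4 there were 481 higher and 672 lower. limma voom on estimated reads also called 0 in each direction, with 167 higher and 178 lower at an unadjusted p under 0.05. The 3 melatonin animals all lay above the 3 vehicle animals for 410 genes and all below for 439, together 8.4%, where chance gives 10%. With 3 animals against 3, no two-sided exact permutation test of a single gene can go below p = 0.1.

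All values that follow are FPKM as mean ± SD with n = 3 animals per group, and log2 changes are melatonin minus vehicle on the log2(FPKM + 1) scale with their standard error. The following genes are described by their values, since none passed the test. Acaa2 stood at 84.1 ± 4.63 after vehicle and 127 ± 7.97 after melatonin (log2 change 0.59 ± 0.09, limma adjusted p = 0.480). Pkib, an inhibitor of the cAMP-dependent protein kinase, stood at 0.723 ± 0.531 and 7.20 ± 2.19 (log2 change 2.26 ± 0.31, limma adjusted p = 0.281), which corresponds to at most 6.2 estimated reads in a vehicle library and at least 24.8 in a melatonin library. Serpina3n stood at 14.4 ± 10.3 and 54.9 ± 14.0, Tnfsf10 at 5.78 ± 3.06 and 16.2 ± 0.503, and Slpi at 2.88 ± 0.663 and 7.15 ± 1.58. The interferon-inducible gene Ifi27l2b stood at 21.2 ± 4.58 and 63.1 ± 20.7. The folate enzyme Ggh stood at 7.01 ± 0.854 and 14.0 ± 3.29, Mitd1 at 8.86 ± 0.426 and 14.1 ± 1.01, the homeobox gene Otx1 at 1.70 ± 0.523 and 4.36 ± 0.450, and the mRNA 3' end nuclease Cpsf3 at 22.5 ± 0.978 and 37.0 ± 7.45. These last 8 genes had limma adjusted p-values of 0.710 for Ifi27l2b and 0.972 for the others. Without vehicle animal 1, Tnfsf10 passed the threshold with a log2 change of 1.78 (limma adjusted p = 0.0391). Without melatonin animal 4, Ifi27l2b did so with a log2 change of 1.79 (limma adjusted p = 0.0471). Serpina3n belongs to a family of near-identical copies, so its reads are not certain to be its own.

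Among the genes ranked first in the other direction, Hspa1a stood at 21.9 ± 3.15 after vehicle and 8.13 ± 1.38 after melatonin (log2 change -1.33 ± 0.17, limma adjusted p = 0.254). A near-identical copy of this gene, picked out after its values were seen, has a row of its own with a log2 change of -0.63 ± 0.16 (limma adjusted p = 0.972), and how reads were divided between the 2 rows is uncertain. Per1 stood at 48.7 ± 2.35 and 30.9 ± 6.06, with each melatonin animal below each vehicle animal (log2 change -0.66 ± 0.15, limma adjusted p = 0.972). Dbp stood at 157 ± 31.2 and 103 ± 11.2, and Klf9 at 31.4 ± 4.39 and 20.6 ± 2.80. The polyamine regulator Oaz2 stood at 34.2 ± 1.37 and 23.2 ± 2.22, Fahd2a at 15.7 ± 2.50 and 9.14 ± 1.02, the potassium channel partner Kcnip2 at 2.16 ± 0.210 and 0.477 ± 0.278, and the monocarboxylate transporter Slc16a12 at 3.26 ± 0.621 and 1.28 ± 0.257. Zp2, a glycoprotein of the egg coat, was listed at 2.53, 3.34 and 3.90 after vehicle and at 1.36, 0.53 and 0 after melatonin. The smallest p of all belonged to the microRNA precursor Mir3074, listed at 3.45, 3.76 and 3.49 after vehicle and at 0 in each melatonin animal. Its vehicle values correspond to 1 estimated read per library.

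**Figure D1:**
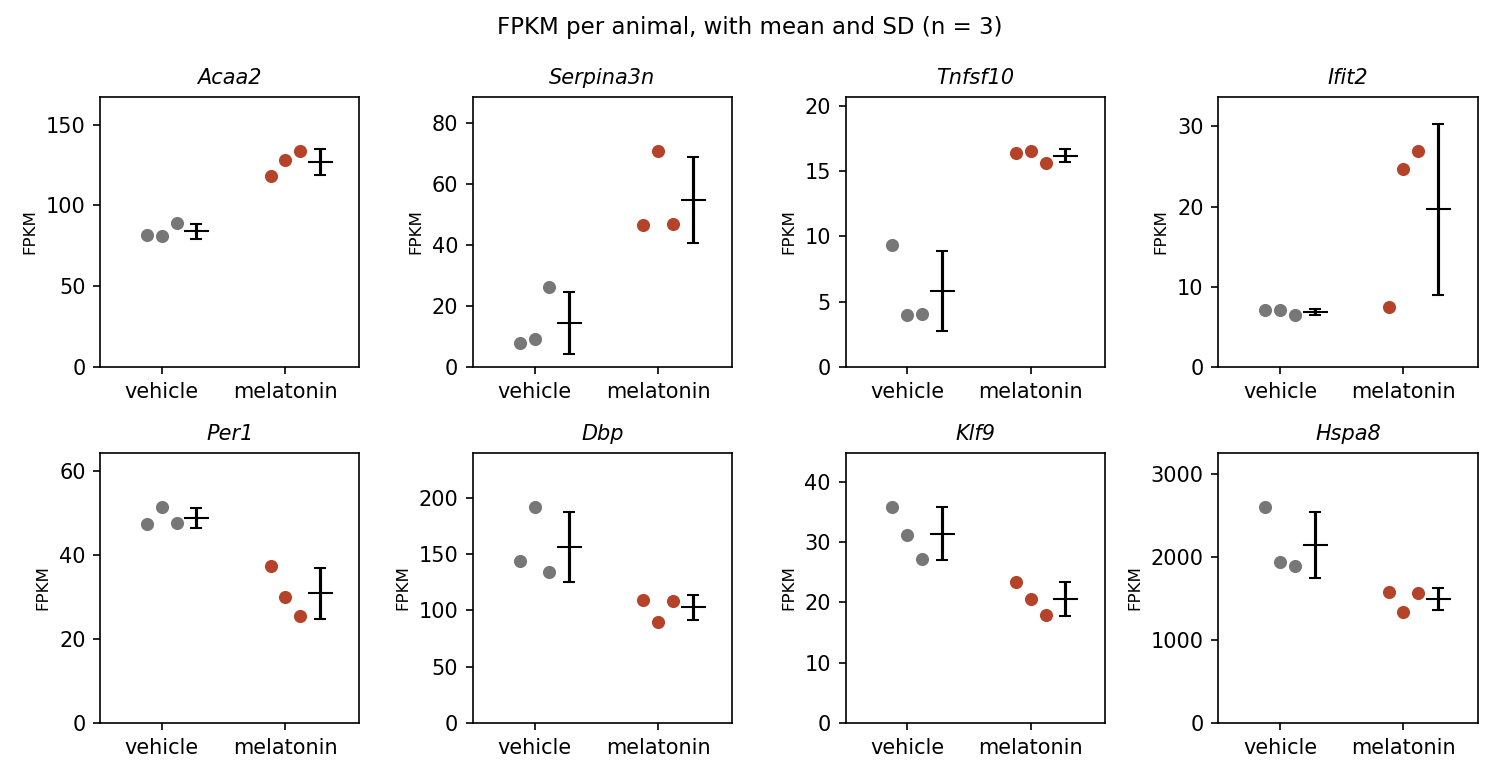
FPKM of 8 genes in each animal (vertical axes, linear, from 0), with vehicle in grey and melatonin in red; each dot is 1 animal and the black marks are the mean and SD with n = 3. The 3 melatonin animals lie beyond the 3 vehicle animals for all 8 genes, by a small margin for Ifit2 in animal 4 (7.45, against at most 7.09 after vehicle), and none of the 8 passed the adjusted threshold.

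Interferon-stimulated genes, which encode antiviral effectors and their regulators, were higher in melatonin animals 5 and 6 and at the vehicle level in melatonin animal 4. Over the 36 measured members the median log2 difference from the vehicle mean was 1.20 in animal 5, 1.08 in animal 6 and -0.10 in animal 4, and the vehicle animals lay at 0.14, -0.14 and -0.08. Above all 3 vehicle animals were 33 members in animal 5, 34 in animal 6 and 1 in animal 4. Ifit2 was listed at 7.45, 24.63 and 26.99 in animals 4, 5 and 6, against 7.05, 7.09 and 6.46 after vehicle. Ifit1 was listed at 0.54, 12.10 and 24.40 against 1.05, 0.14 and 0.13, and Gbp5 at 2.06, 6.75 and 4.93 against 1.61, 2.19 and 1.02. Irf9, a transcription factor of the type I interferon pathway, was listed at 20.13, 37.01 and 40.78 against 19.81, 23.14 and 17.54. The list's median log2 change was 0.66, with 35 of 36 members positive, 0 past 0.05 over all genes and 0 adjusted over the list alone. It passed limma camera with a preset correlation of 0.01 (adjusted p = 2.24e-15). With the correlation estimated from these data, 0.59, it did not pass (limma camera adjusted p = 0.674). At such a correlation the preset p-value overstates the evidence, since it treats the members as nearly independent. Ifit genes have near-identical copies, and their values carry that uncertainty.

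Immune genes of other kinds differed by animal as well. Markers of T and NK cells had a median log2 change of 0.50 over 10 members, of which 7 reached 1 FPKM after vehicle too, and animals 4, 5 and 6 lay at -0.07, 0.73 and 0.98 from the vehicle mean and the vehicle animals at 0.34, -0.08 and -0.31. The list passed limma camera at an adjusted p of 0.00506, against an adjusted p = 0.674 with an estimated correlation. Cd3e, a chain of the T cell receptor complex, stood at 1.35 ± 0.565 after vehicle and 3.49 ± 1.37 after melatonin, and Gzmb, the granule protease, was listed at 0.79, 0.65 and 0 against 0.41, 2.17 and 7.52. Genes of MHC class II presentation had a median log2 change of 0.51 over 11 members, with animal 5 at 1.48, animal 4 at 0.23 and animal 6 at -0.29 and the vehicle animals at 0.19, -0.16 and 0.00 (limma camera adjusted p = 0.0108, and adjusted p = 0.674 with an estimated correlation). Cd74, the invariant chain, was listed at 158.08, 630.83 and 86.24 in animals 4, 5 and 6, against 164.03, 75.43 and 59.88. Inflammatory mediators had a median log2 change of 0.19 over 12 members, with animal 6 at 0.45, animal 5 at 0.10 and animal 4 at -0.02 and the vehicle animals at 0.28, -0.03 and -0.32 (limma camera adjusted p = 0.0384, and adjusted p = 0.674 with an estimated correlation). Il1a was listed at 0.29, 1.42 and 16.26 in animals 4, 5 and 6 and at 0.86, 0.47 and 0.14 after vehicle, so it passed the filter through melatonin animals. With a filter of at least 1 FPKM in at least 3 animals, which Il1a does not meet, the list did not pass (limma camera adjusted p = 0.105). Macrophage and dendritic cell markers had a median log2 change of 0.00 over 9 members (limma camera adjusted p = 0.718).

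Genes of the core clock and its output had a median log2 change of -0.20, with 15 of 19 members negative. The median difference from the vehicle mean was -0.22 in animal 5, -0.37 in animal 6 and 0.04 in animal 4, and the vehicle animals lay at -0.10, 0.14 and -0.02. Members below all 3 vehicle animals numbered 9, 14 and 2 in these animals. The list passed limma camera with the preset correlation (adjusted p = 0.00105) and not with an estimated one (limma camera adjusted p = 0.674). Per1 and Dbp were the 2 members past 0.05 adjusted over the list alone, and 0 were past it over all genes. Ciart, a repressor of the clock, stood at 43.0 ± 16.9 and 25.5 ± 3.61, and Bhlhe40, another repressor, at 112 ± 12.9 and 83.0 ± 27.3. Per2 stood at 116 ± 11.5 and 97.5 ± 19.0 and Nr1d1, also called Rev-erb alpha, at 97.8 ± 33.7 and 66.2 ± 4.46. Bmal1, their positive partner in the loop, stood at 7.33 ± 1.78 and 8.37 ± 1.85 (log2 change 0.17 ± 0.22, limma adjusted p = 0.974). Glucocorticoid-induced genes, a list that shares Per1 with the clock list, had a median log2 change of 0.01 and a mean of -0.06 over 17 members (limma camera adjusted p = 0.775), with the test's direction down. Per1 and Klf9 were the 2 members past 0.05 adjusted over that list alone. Cebpd stood at 3.80 ± 1.54 and 10.8 ± 5.88, and Sgk1 at 523 ± 58.8 and 417 ± 193.

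Heat shock genes had a median log2 change of -0.06 and a mean of -0.17 over 13 members, 8 of them negative (limma camera adjusted p = 0.0445, and adjusted p = 0.675 with an estimated correlation). Animals 4, 5 and 6 lay at -0.30, -0.03 and -0.06 from the vehicle mean and the vehicle animals at 0.20, -0.02 and -0.18, so animal 4 lay below them and animals 5 and 6 did not. Hspa1a and the constitutive chaperone Hspa8 were the 2 members past 0.05 adjusted over the list alone, with Hspa8 at 2143 ± 400.3 after vehicle and 1489 ± 132 after melatonin. The co-chaperone Dnaja1 stood at 60.8 ± 10.9 and 45.4 ± 9.39, while the mitochondrial chaperone Hspd1 stood at 90.8 ± 17.8 and 111 ± 30.1. Without melatonin animal 4 the list's direction turned (limma camera adjusted p = 0.992). Genes of the unfolded protein response had a median log2 change of 0.15 over 20 members, with animals 4, 5 and 6 at -0.06, 0.33 and 0.22 and the vehicle animals at 0.03, 0.02 and -0.08 (limma camera adjusted p = 0.0324, and adjusted p = 0.674 with an estimated correlation). The endoplasmic reticulum chaperone Hsp90b1 was listed at 233.75, 447.34 and 450.60 in animals 4, 5 and 6 and at 270.35, 261.28 and 242.97 after vehicle, and the calcium-binding chaperone Calr at 725.74, 1129.09 and 1118.87 against 801.34, 797.22 and 760.63.

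Cell cycle genes had a median log2 change of 0.17 over 33 members, 23 of them positive (limma camera adjusted p = 0.00105, and adjusted p = 0.712 with an estimated correlation). The median difference from the vehicle mean was 0.57 in animal 5, 0.08 in animal 4 and -0.15 in animal 6, and the vehicle animals lay at 0.25, -0.14 and -0.19, so animal 5 lay above them and animals 4 and 6 did not. Of the members with the smallest p, the replication licensing factor Mcm4 stood at 12.4 ± 1.42 and 18.9 ± 3.27, Mcm3 at 8.96 ± 1.33 and 12.9 ± 0.814, and Mcm6 at 16.0 ± 2.48 and 21.9 ± 2.23, and each melatonin animal lay above each vehicle animal for the 3 genes. Cholesterol synthesis genes had a median log2 change of 0.16 over 24 members, with 16 above all vehicle animals in animal 6, 10 in animal 5 and 3 in animal 4 (limma camera adjusted p = 0.0164, and adjusted p = 0.674 with an estimated correlation). Animals 4, 5 and 6 lay at -0.05, 0.15 and 0.36 from the vehicle mean and the vehicle animals at -0.04, 0.07 and -0.02. Dhcr7 stood at 25.3 ± 3.91 and 32.5 ± 2.58, Hmgcs1 at 71.8 ± 11.2 and 105 ± 38.2, and Tm7sf2, a sterol reductase, at 19.4 ± 2.44 and 13.4 ± 2.45. Without melatonin animal 6 the direction of this list turned (limma camera adjusted p = 0.973). Immediate early genes had a median log2 change of 0.16 over 25 members, 21 positive and 4 negative (limma camera adjusted p = 0.00506, and adjusted p = 0.674 with an estimated correlation). Animals 4, 5 and 6 lay at 0.11, 0.01 and 0.33 from the vehicle mean and the vehicle animals at -0.06, -0.13 and 0.12, so animal 6 lay above them and animals 4 and 5 did not. Gadd45b, the member with the smallest p, had values in the other direction, at 26.5 ± 2.77 and 20.1 ± 5.53, with each melatonin animal below each vehicle animal (log2 change -0.41 ± 0.21, limma adjusted p = 0.972). Egr1 was listed at 5.96, 5.79 and 28.44 in animals 4, 5 and 6 and at 4.50, 5.11 and 6.25 after vehicle.

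2 lists of the epithelium's own functions were called lower by small amounts. Nuclear-encoded subunits of oxidative phosphorylation had a median log2 change of -0.06 over 33 members, 28 of them negative (limma camera adjusted p = 0.0108, and adjusted p = 0.687 with an estimated correlation). Animals 4, 5 and 6 lay at -0.12, -0.02 and -0.09 from the vehicle mean and the vehicle animals at 0.02, -0.07 and 0.05. Ndufa9 stood at 110 ± 9.85 and 95.3 ± 5.83. Transporters and channels for ions, water and short-chain fatty acids had a median log2 change of -0.09 over 34 members, 25 of them negative (limma camera adjusted p = 0.0384, and adjusted p = 0.674 with an estimated correlation). Animals 4, 5 and 6 lay at -0.01, -0.10 and -0.12 and the vehicle animals at -0.03, 0.11 and -0.04. Neither list passed with median-of-ratios scaling (limma camera adjusted p = 0.0745 and 0.0737). The sodium pump subunit Atp1b1 stood at 1614 ± 45.4 and 1402 ± 100.6, the epithelial sodium channel subunit Scnn1a at 288 ± 18.6 and 252 ± 11.9, the chloride exchanger Slc26a3 at 1181 ± 152 and 1002 ± 57.4, and carbonic anhydrase Car2 at 879 ± 152 and 673 ± 217.

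Among the 18 lists that limma camera did not call were the markers of absorptive colonocytes (median log2 change 0.00, mean -0.07, adjusted p = 0.689), goblet cells (median -0.04, mean 0.13, adjusted p = 0.954), enteroendocrine cells (median 0.11, adjusted p = 0.186), crypt base and stem cells (median -0.06, adjusted p = 0.954), tuft cells (median 0.08, adjusted p = 0.689) and smooth muscle (median 0.03, mean -0.01, adjusted p = 0.954). Fatty acid oxidation genes had a median log2 change of -0.10 over 23 members (limma camera adjusted p = 0.954), and Acaa2 was the member past 0.05 adjusted over the list alone. Of the genes of melatonin synthesis and metabolism, Tph1 stood at 4.25 ± 0.440 and 4.91 ± 0.819, Sult1a1 at 4.29 ± 0.894 and 3.39 ± 0.819, and Nqo2 at 16.6 ± 3.35 and 17.0 ± 5.97. The receptor genes Mtnr1a and Mtnr1b had no row in the table used here. Red blood cell genes, too few for a list test, had a median log2 change of -0.42 over 4 members. Hbb-b1 stood at 4.26 ± 1.27 and 1.74 ± 0.775 and was past 0.05 adjusted over the list alone, but not over all genes (limma adjusted p = 0.972). Its values correspond to at most 12.7 estimated reads in a vehicle library and at most 5.9 in a melatonin library.

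**Figure D2:**
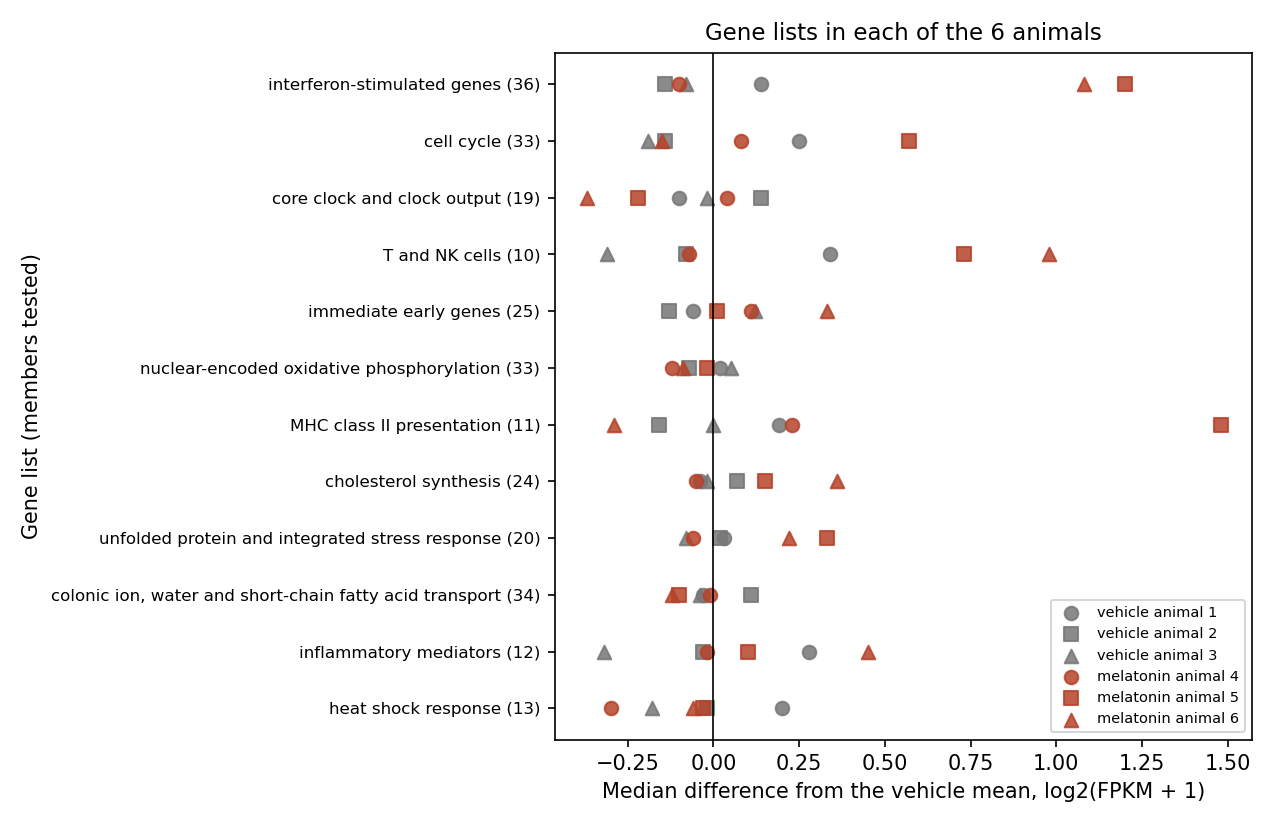
Median difference from the vehicle mean over the members of each of the 12 gene lists called by camera with the preset correlation (horizontal axis, log2(FPKM + 1) scale), with vehicle animals in grey and melatonin animals in red. The interferon list lies at 1.20 and 1.08 in melatonin animals 5 and 6 and at -0.10 in animal 4, beside the vehicle animals, and the class II list lies at 1.48 in animal 5 and -0.29 in animal 6.

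In all, limma camera called 12 of 30 lists with the preset correlation, 8 higher and 4 lower. Over all genes, 0 members of the 12 lists passed 0.05, and adjusted over the list alone 2 passed in the clock list, 2 in the heat shock list and 0 in each of the other 10. No list passed with a correlation estimated from the data (smallest adjusted p 0.674) or in the fry rotation test of limma (smallest adjusted p 0.638). The estimated correlations of the 12 called lists ran from 0.06 for ion transport to 0.70 for the cell cycle, all above the preset 0.01. The preset counts genes that vary together as nearly independent, so its p-values overstate the evidence for these lists. The estimated setting can also raise p without a higher correlation. Fatty acid and triglyceride synthesis, a list not called, had an estimated correlation of -0.02. Its unadjusted limma camera p went from 0.0407 with the preset to 0.0912. With 3 animals per group, 0 lists in the stricter tests does not show that no list changed. The leading principal component held 37.9% of the variance and put melatonin animal 6 at 35.6, melatonin animal 5 at 11.4, vehicle animal 1 at -0.8 and the remaining animals between -16.7 and -13.5, so it did not separate the 2 groups. Correlations between libraries were 0.956 to 0.976 within groups and 0.955 to 0.978 between groups (Pearson's r across genes, which are not independent replicates), and no 2 libraries held the same values.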

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

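No paired analysis was possible because the labels number the vehicle animals 1 to 3 and the melatonin animals 4 to 6, so the groups share no number. The unsummed transcripts, the length limit and the list tests with upper-quartile scaling, pseudocount 0.1 and voom were added after the data were seen; the DESeq2 alternative was not run, since it needs counts. limma called 0 genes higher and 0 lower under each other setting that kept all 6 animals, except for 1 lower without a filter on low values, Mir3074 at about 1 read per vehicle library (limma adjusted p = 0.0107). Sample quality weights also gave 0 and 0, with 383 higher and 364 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.0927. Leaving out 1 animal at a time gave 0 to 4 genes higher and 0 to 1 lower, and the numbers at an unadjusted p under 0.05 ran from 125 to 481 higher and from 118 to 672 lower, both highest without melatonin animal 4. Without vehicle animal 1 the 3 higher were Fam111a, Scgb1a1 and Tnfsf10. Without melatonin animal 4 the 4 higher were Ifi27l2b, Ifit2, Oasl2 and the microRNA precursor Mir126a, and without vehicle animal 2 the 1 lower was Mir3084a. Fam111a, Scgb1a1, Oasl2 and both last-named precursors were picked out after their values were seen.

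The 12 gene lists became 0 with an estimated correlation, 0 with fry and 7 with median-of-ratios scaling, which moved library values by at most a factor of 0.938; the cause was not tested. That scaling lost oxidative phosphorylation, the unfolded protein response, ion transport, inflammatory mediators and heat shock, with adjusted p-values from 0.0737 to 0.0759. Upper-quartile scaling gave 8 lists, ranks 9, the stricter filter 10, and voom and pseudocount 0.1 gave 12. Over the 8 settings with all animals, heat shock was called in 2, the unfolded protein response, ion transport and inflammatory mediators in 3, oxidative phosphorylation in 5 and the other 7 lists in 6. Leaving out 1 animal gave 7 to 10 lists, with 7 without vehicle animal 2, vehicle animal 3 or melatonin animal 6. The interferon list passed limma camera in 6 of 6 of these fits, with adjusted p-values from 2.98e-31 to 2.60e-06. The clock list also passed in 6 of 6 (limma camera adjusted p-values from 0.000262 to 0.0137), and the other 10 lists in 3 or 4. Each of these fits used the preset correlation and kept melatonin animal 5 or 6, where both patterns lie. Passing all 6 therefore does not show that the patterns follow the treatment. Adjusted p-values of the heat shock list ranged from 0.00157 to 0.992 and its direction turned without melatonin animal 4, where it was 0.992. Those of cholesterol synthesis ranged from 0.000139 to 0.973, and its direction turned without melatonin animal 6, where it was 0.973; the cause of neither was tested. Of the 80 named genes in 1116 combinations of gene and setting, 1108 kept direction and side of the threshold, and 4 passed it. The other 4 were Nqo2, at 0.01 as reported, with -0.01 in voom, -0.13 with quality weights, and -0.25 to 0.16 when 1 animal was left out. Most of the 80 were picked by small p in the same animals, and staying short of the threshold counted as kept. The 1108 therefore do not show stability. Depth limits genes near 1 FPKM, which rest on few reads per library.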

Other observations

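Most tests in this part were chosen after the results were seen: those on the interferon pattern, the clock pattern, the listed zeros, the annotation terms and the genes at separate levels. Only the counts of genes and of lists under other splits of the animals were set out beforehand.

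Of 633 biological process terms in the annotation that the table carries, with 10 to 500 tested genes each, 4 passed limma camera with the preset correlation, and 0 with an estimated one (adjusted p = 0.998 for each). The one with the smallest p carries no name in the table; its 53 members had a median log2 change of 0.11, with melatonin animals 4, 5 and 6 at 0.02, 0.24 and 0.10 from the vehicle mean (limma camera adjusted p = 0.00379). Ribosome biogenesis genes had a median log2 change of 0.09 over 62 members, with melatonin animals 4, 5 and 6 at 0.03, 0.13 and 0.15 from the vehicle mean (limma camera adjusted p = 0.00963). Lymphocyte activation genes had a median of 0.23 over 14 members and lay at 0.19, 0.20 and 0.17 in the 3 animals (limma camera adjusted p = 0.00963). Positive regulation of cytokine synthesis had a median of 0.20 over 25 members (limma camera adjusted p = 0.0313).

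A search of 10137 features for genes whose animals fall on 2 levels, at least 2.5 apart on the log2(FPKM + 1) scale with at least 2 animals on each, found 9 among those with a transcript of at least 200 bases. Ndufa10l1, related to a subunit of complex I, was listed at 31.06 in vehicle animal 1 and 30.66 in melatonin animal 4 and at 0 in the other 4 animals. Alpi, an intestinal alkaline phosphatase, was listed at 7.91 and 16.87 in the same 2 animals and at 0 in the other 4. Fam111a was listed at 2.13 and 1.88 in vehicle animals 2 and 3 and between 47.48 and 78.97 in the rest, and Gpank1 at 112.27 and 165.63 in vehicle animal 2 and melatonin animal 5 and between 13.80 and 17.76 in the rest. Pla2g2a, a secreted phospholipase with antibacterial activity, ran from 47.27 in vehicle animal 3 to 3212.35 in melatonin animal 6, with vehicle animal 1 at 1084.46 and melatonin animal 5 at 566.62. The others were Retnla, Ifit1, Ubd and Rpph1. The metallothioneins, picked out after their values were seen, missed this bound. Mt1 was listed at 727.87, 808.22 and 821.44 in vehicle animals 2 and 3 and melatonin animal 5 and at 273.90, 263.72 and 251.33 in the other 3, and Mt2A at 208.11, 205.87 and 225.05 against 52.10, 48.55 and 52.69.

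The interferon list was higher after melatonin by a median of 0.66, with animal 4 at the vehicle level. That description comes from the values themselves and was not tested apart from them. More macrophages and dendritic cells after melatonin stays open. Their 9 markers had a median log2 change of 0.00, with a 95% bootstrap interval over members from -0.40 to 0.53. These markers lay at 0.16, 0.33 and -0.06 from the vehicle mean in animals 4, 5 and 6, and at 0.24, -0.30 and 0.00 in the vehicle animals. Animal 6, high in the interferon list, thus lay within the vehicle range for them, but this rests on 1 library. More T and NK cells after melatonin may go with the pattern and stays open as well. The 10 markers had a median of 0.50, with an interval from 0.08 to 0.95 around the bound of 0.3 set for it. Both intervals resample members, which vary together, with an estimated correlation of 0.41 for the T and NK markers and 0.23 for the macrophage markers. They do not measure the spread between animals. With 10 splits of the 6 animals a share under 0.05 cannot be reached. Of the 10, 2 gave a median as large, 0.66 for the real one and 0.93 for the highest other. Splits that set melatonin animals 5 and 6 with vehicle animal 3, 2 or 1 gave 0.64, 0.62 and 0.93. Their unadjusted limma camera p-values with the preset correlation were 2.35e-20, 1.5e-17 and 3.01e-23, each smaller than 7.47e-17 for the real split. The pattern was itself described from animals 5 and 6, so splits that keep them together had to give medians of similar size. Both animals received melatonin. These splits therefore do not separate a response in animals 5 and 6 from another difference between animals.

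The clock list was lower by a median of 0.20 in size, and the highest other split gave 0.30, with 3 of 10 splits as large and too few splits for a share under 0.05. In the real split its unadjusted limma camera p with the preset correlation was 0.000105, the smallest of the 10. The split that sets vehicle animal 1 with melatonin animals 5 and 6 gave 0.000346. That setting treats the members as nearly independent, and 1 split of the 10 must rank first. A later time of death in the melatonin animals might lower the genes that decline early in the night and raise those that come up later. The labels give 4 h after injection for both groups. The 9 early genes are members of the list already called lower, so their level cannot count as support. The 9 early genes had a median log2 change of -0.46, and Bmal1, Npas2, Clock and Nfil3 a median of 0.08, but these 4 ranged from -0.18 to 0.56 and Nfil3, the highest, lay below the filter at 0.16 to 1.85 FPKM. Without it the 3 tested genes had a median of -0.01 and ranged from -0.18 to 0.17, so this explanation is not decided; the requirement that each later gene lie above 0 was added after these values were seen, and without that addition the median of the 4, 0.08, would have met what the explanation predicts. A direct effect of melatonin on the clock genes, which the design names, was not tested apart from it and stays open.

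Of the transcripts in the authors' deposited table, 49 had a probability of at least 0.8, a bound chosen here, 37 with a higher and 12 with a lower melatonin mean. Among the 49, 14 were listed at 0 in at least 1 animal, 13 of them from genes with a further listed transcript. For 12 of the 13 the summed gene changed by less than 1 on the log2 scale. Reads divided between transcripts of 1 gene may account for these, but a real shift between transcripts would leave the sum unchanged as well. This count cannot tell them apart. The bound of 1 was also easy to meet, since the median residual SD over the features tested was 0.213 on the log2 scale. For 1 Xbp1 transcript the authors' deposited table lists 0, 0 and 0 after vehicle and 23.00, 0 and 57.39 after melatonin, while the summed gene had a log2 change of -0.04. Pkib was the exception, with 2.26 for the summed gene.

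With 0 genes in the real split, each of the 10 splits of the 6 animals necessarily gives as many, so this count decides nothing; the highest other gave 3. For the lists, 2 of the 10 gave at least 12, the real value, and the highest other gave 14, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 380 genes, and the one that sets vehicle animal 1 with melatonin animals 5 and 6 gave 1452. This points to a structure of the samples that the treatment groups do not match in full. It was picked as the highest of the 10 and keeps melatonin animals 5 and 6 together, so it is not separated from a response in these 2 animals, and it was not tested further. The labels used here give no batch or day.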
